A study of Sus scrofa with 12 samples.

How the data were processed

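Uterine small RNA libraries of 12 neonatal gilts were analysed, 4 each of PND0, PND2N and PND2R, grouped by the feeding and age given in the labels. Replicates were numbered in accession order, so the numbers pair no samples. Per the labels' protocols, total RNA was isolated with a column kit, 500 ng per animal entered a NEBNext small RNA kit with 6 PCR cycles, and pooled libraries were read on an Illumina HiSeq as single ends of 50 bp. The submitters' processing notes name the Sscrofa 10.2 genome and FastQC; the aligner, the counting tool and the normalization were not given in the sources used here.

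The deposited table holds a normalized expression signal for 420 miRNA rows (362 names, 51 of them with more than 1 precursor row). From the values, the deposited signal is a read count divided by 1 scaling factor per library, and values under 1 were raised to 1. Whole reads were recovered from the steps between low values: all values of up to 1000 reads came out whole within 0.1 of a read in every library (100%), and at least 95.9% of all values above the floor did. The floor hides up to 12 reads in the deepest libraries and none in the 4 shallowest, and values at the floor entered the count tests as 0 reads. Depth ranged from 37462 to 12159233 reads; 1 read is worth 26.7 rpm in the shallowest library. Levels in rpm are reads per 1000000 recovered miRNA reads. No unique molecular identifiers were used, so counting intervals cover counting error only.

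The main test was limma 3.58.1 (empirical Bayes with trend, R 4.3.3) on log2(value + 1), with 1 coefficient per group over all 12 libraries (9 residual degrees of freedom), two-sided, Benjamini-Hochberg adjusted, with a threshold of 0.05. Fold changes on this scale understate the change of low miRNAs. Rows above the floor in at least 4 libraries were tested: 268 rows (236 names), leaving out 152, of which 134 were at the floor in every library. miRNA lists fixed with the design, 24 in all, were tested by limma's camera with a preset correlation of 0.01 where at least 3 rows were measured (22 lists), with the correlation estimated, with fry, a rotation test of a list's own direction, and on limma voom values of the recovered reads. The design, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The design named edgeR for counts; the unit called for limma, and edgeR 4.0.16 (quasi-likelihood, TMM factors 0.839 to 1.09), limma voom and DESeq2 1.42.0 ran on the recovered reads, the first 2 of these chosen after seeing the data.

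The text names the 10 miRNAs with the smallest limma p in each comparison, up to 4 members of each called list and the 10 most abundant miRNAs; where it names others, they were chosen after their values were seen. Rows of near-identical copies can share reads and are uncertain. No coordinates are given, because the gene table at hand uses another pig assembly. Chi-square per degree of freedom between replicate pairs was 2.98 to 1093 over 18 pairs, and no 2 columns were identical. The tests were tried on simulated counts for the 268 rows with the real means and depths and 60 changed rows in each of 5 runs. Rows were drawn independently of each other. Recovery can be lower where fewer rows change or rows vary together between libraries, which was not simulated. False calls by edgeR were 1.08% of unchanged rows for PND2N against PND0, 0.985% for PND2N against PND2R and 1.97% for PND2R against PND0, and 0 by limma. Alternatives covered re-centring, quantile normalization, pseudocounts of 0.1 and 5, filters, library weights, the groups in the fit, thresholds, single rows per name and each library left out. Figures were drawn with matplotlib 3.10.9.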

Results

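Small RNA was sequenced from the uterus of neonatal gilts, young female pigs of mixed Landrace, Yorkshire, Duroc and Hampshire breeding. The 12 libraries came from separate animals per the labels and formed 3 groups of 4. The PND0 gilts were taken within 1 h of birth and had not nursed. The PND2N gilts nursed freely for 48 h and the PND2R gilts took a commercial milk replacer for the same time, and both were collected at 50 h of age. The series title names age and lactocrine (milk-borne) sensitivity of uterine miRNAs as its subject, so PND2 against PND0 asked about age, and PND2N against PND2R asked about nursing at 1 age. Both PND2 groups had also been fed for 48 h, and PND0 had not nursed. The age comparisons below therefore cannot tell age apart from feeding after birth.

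The recovered miRNA reads numbered 464476, 3561682, 12159233 and 375882 in PND0 replicates 1 to 4. They numbered 11807838, 37462, 8400976 and 242550 in PND2N, and 74799, 69816, 47992 and 9395582 in PND2R. Depth thus spanned 325-fold, and 4 libraries, 3 of them PND2R and 1 PND2N, held under 100000 reads. The normalized totals followed depth: the 5 libraries over 1000000 reads had totals of 720912 to 1048570, and the other 7 had 172788 to 445246 (log2 difference 1.80, two-sided exact permutation p = 0.00126 over 792 splits). Pearson correlations of log2 levels across miRNAs, which are not independent replicates, were 0.953 to 0.994 between libraries over 200000 reads and 0.854 to 0.940 for pairs with a shallower library.

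**Figure D1:**
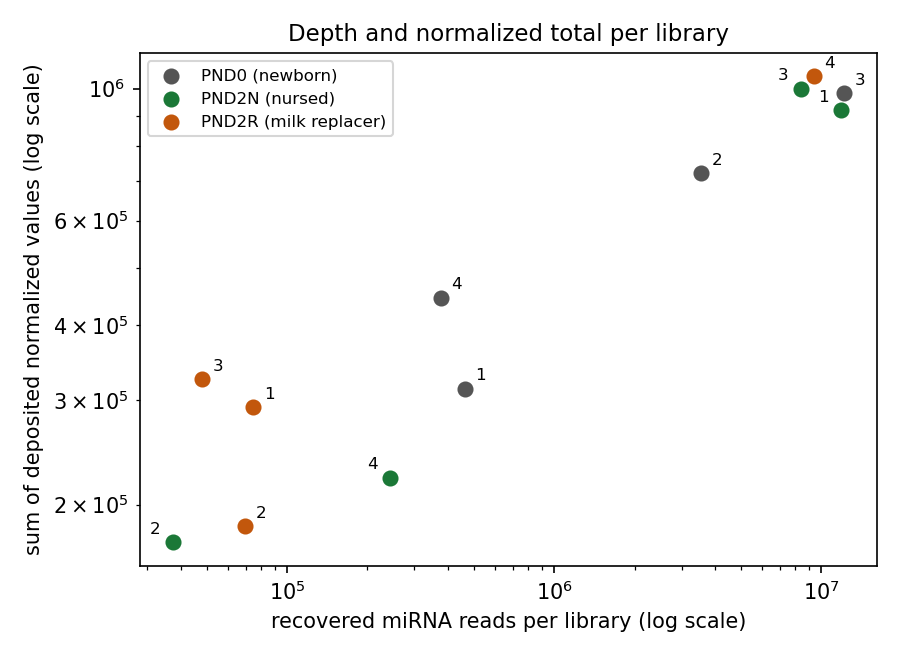
Sum of deposited normalized values against recovered miRNA reads for each of the 12 libraries, both on log axes, with replicate numbers beside the points and colours for PND0, PND2N and PND2R. The 5 libraries over 1000000 reads have the 5 highest normalized totals, and 3 of the 4 PND2R libraries lie under 100000 reads.

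The most abundant miRNA of the neonatal uterus was miR-143-3p, and miRNAs of mesenchyme and the HOX clusters were also among the first 10. miR-143-3p, a smooth muscle miRNA, took 16.9% ± 4.83 (SD, n = 12) of the miRNA reads, followed by miR-99a at 9.04% ± 2.16 and miR-27b-3p at 6.94% ± 1.03. The HOX cluster miRNA miR-10b held 4.72% ± 1.01, the mesenchymal miR-199a-3p 4.32% ± 0.769 and its other arm miR-199a-5p 2.16% ± 0.647. The miR-199a shares are each for 1 row. Another row exists for each arm and can share reads, so the ranks of both arms are uncertain. miR-125b held 3.33% ± 0.863, miR-21 3.07% ± 0.672, miR-148a-3p 3.02% ± 0.731 and let-7i 2.68% ± 0.512. These 10 were ranked by mean deposited value, in which deep libraries weigh more; by mean share of reads let-7f, at 24696 ± 2791 rpm in PND0 for 1 of its rows, precedes miR-199a-5p. The 10 most abundant rows of each library, which can hold 2 rows of 1 miRNA, took 51.5% to 68.3% of its reads.

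In nursed gilts at 50 h against newborns, miR-206, a skeletal muscle miRNA, averaged 3.77 ± 5.56 rpm (reads per 1000000 miRNA reads; SD, n = 4) against 26.2 ± 9.35. miR-210, induced by hypoxia, stood at 87.9 ± 41.9 rpm against 191 ± 70.3, and the epithelial miR-205 at 481 ± 278 against 812 ± 93.3. In the other direction miR-1, a striated muscle miRNA, stood at 3104 ± 769.6 rpm against 2167 ± 507, and miR-143-3p at 196907 ± 64659 against 133901 ± 36517. None of these passed over all 268 miRNA rows tested.

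The log2 fold change of miR-206 was -1.98 ± 0.70 (SE) on the deposited values by limma (adjusted p = 0.962) and -1.90 ± 0.50 on recovered reads by edgeR (adjusted p = 0.116). PND2N lay above PND0 in 0 of 16 pairs of libraries, but miR-206 was at the floor in PND2N replicates 2 and 4, and in the first of these 1 read is worth 26.7 rpm. By edgeR the log2 fold change of miR-1 was 0.67 ± 0.23 (above in 16 of 16 pairs), that of miR-143-3p 0.75 ± 0.25 and that of miR-378, which is encoded within a metabolic regulator gene, 0.66 ± 0.23, each at an adjusted p of 0.344. miR-210 was at -0.80 ± 0.29 (adjusted p = 0.365), miR-205 at -0.53 ± 0.27 (adjusted p = 0.806) and miR-339 at -0.61 ± 0.24 (adjusted p = 0.525). miR-1, miR-143-3p and miR-378 were chosen after their values were seen, by the smallest edgeR p. The other 6 miRNAs that the fixed rule named, miR-202-5p, miR-135, miR-139-3p, miR-708-5p, miR-18b and miR-17-3p, had edgeR adjusted p from 0.266 to 0.989 and also lay at the floor in at least 1 PND2N library.

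Among the fixed lists, striated muscle miRNAs were split between directions. Of their 8 rows 0 passed over all rows, and by limma 1, miR-206, passed when adjusted over the list alone. By edgeR 2 passed adjusted over the list alone, miR-206 with lower and miR-1 with higher levels in PND2N, and the list's medians were -0.38 on deposited values and 0.45 on reads. Of the 14 rows of smooth muscle and mesenchymal miRNAs, 0 passed by either tool, also adjusted over the list alone, and the edgeR median was 0.06. The same held for the 15 rows of the miR-17 cluster and its paralogs (edgeR median -0.15), a group tied to proliferation, and for the 5 hypoxia and stress miRNAs (edgeR median 0.19). In the list of the miR-200 family and other epithelial miRNAs and that of liver and gut miRNAs, edgeR passed 2 rows adjusted over the list alone against 0 by limma. Both were rows of miR-194b-5p, which stayed at the floor in all PND0 libraries and reached at most 14 reads per PND2N library, so that no fold is given. The floor hides up to 12 reads in PND0 replicate 3 and in PND2N replicate 1. Such values entered edgeR as 0 reads, so these passes may come from the floor.

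Neural miRNAs were the only list called by limma's camera test, placed above the other miRNAs (adjusted p = 0.0286; adjusted p = 0.945 with an estimated correlation). Their 18 rows had a median log2 fold change of -0.15 and a mean of -0.16 on deposited values, with 6 above and 12 below 0, while the median over all 268 rows was -0.49. The test's upward sign was therefore relative to the other miRNAs and opposite to the list's median and mean. Of the members named by rule, miR-9 stood at 171 ± 63.8 rpm in PND2N and 194 ± 37.3 in PND0, and its near-copy row miR-9-1 at 173 ± 65.2 and 194 ± 37.1. miR-218-5p stood at 3232 ± 549 against 4238 ± 484 and miR-137 at 2.72 ± 3.16 against 7.22 ± 1.74. For miR-137 this rests on 0 reads in PND2N replicates 2 and 4, and with each group's reads pooled its levels were 5.27 and 5.49 rpm. The call ended without PND0 replicate 2 (adjusted p = 0.259), PND0 replicate 3 (0.0732), PND2N replicate 2 (0.566) or PND2N replicate 4 (0.110). On recovered reads the list was not called (adjusted p = 0.440).

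For PND2N against PND0, limma passed 0 of the 268 rows in this comparison, with 1 at an unadjusted p under 0.05. Chance gives 13.4 for independent rows, but rows can vary together. Of 35 splits of these libraries 20 gave at least as many, and another split gave up to 214. On recovered reads edgeR passed 0 (with 17 at an unadjusted p under 0.05, reached in 17 of 35 splits), limma voom 0 (24) and DESeq2 0 (15). The smallest adjusted p values were 0.962, 0.116, 0.0632 and 0.447 in that order of tools. That of edgeR belonged to miR-194b-5p, near the floor, and to miR-206. The median log2 fold change over all rows was -0.49 on the deposited values and -0.05 on recovered reads, so that fold changes on the deposited scale are relative to a shifted centre. In data simulated at these depths limma recovered 0% of 2-fold, 3.23% of 4-fold and 52.6% of 8-fold changes, and edgeR 52.5%, 93.5% and 97.9%.

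**Figure D2:**
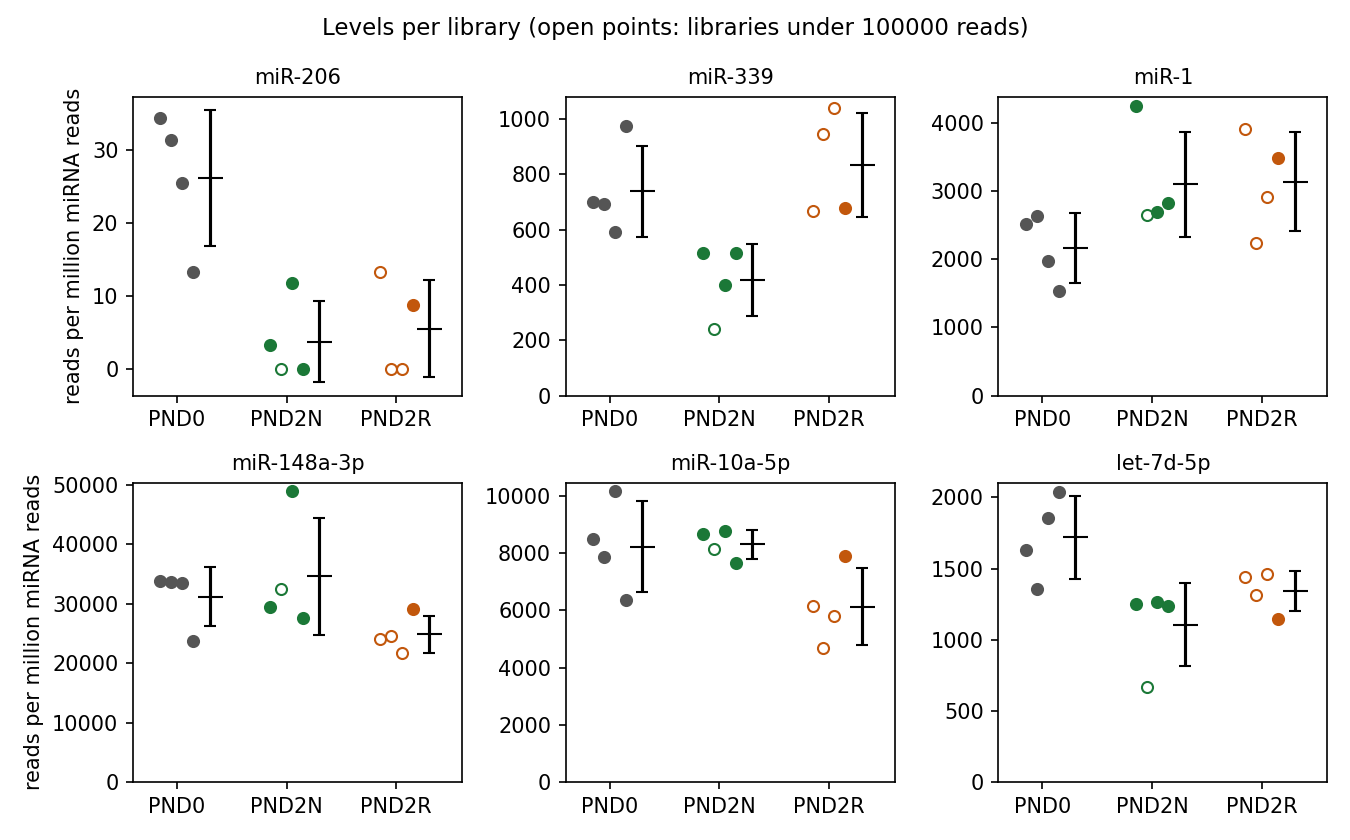
Levels in rpm of 6 miRNAs in each library of PND0, PND2N and PND2R (n = 4 each), with the mean and SD as black bars; open points are the 4 libraries under 100000 reads, and libraries at the floor are drawn at 0. miR-206 averages 26.2 rpm in PND0 against 3.77 in PND2N and 5.52 in PND2R, and none of the 6 passed a test over all rows.

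At 50 h of age, the miRNAs with the smallest edgeR p between nursed and replacer-fed gilts were above the floor in all 12 libraries. miR-148a-3p, among the most abundant miRNAs of milk in many mammals, stood at 34615 ± 9799 rpm (SD, n = 4) in PND2N and 24840.4 ± 3104 in PND2R, and the HOX cluster miRNA miR-10a-5p at 8325 ± 507 and 6137 ± 1339. On the lower side in nursed gilts were miR-339 at 418 ± 130.1 against 834 ± 189 rpm, its overlapping row miR-339-5p at 744 ± 234 against 1311 ± 227, and miR-152, of the same seed family as miR-148a, at 2865 ± 200.5 against 4480.1 ± 389. None passed over all rows, and miR-339 had 9 reads in PND2N replicate 2 and 50 to 66 in the shallow PND2R libraries.

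By edgeR the log2 fold change was 0.62 ± 0.18 for miR-148a-3p (above in 15 of 16 pairs), 0.58 ± 0.19 for miR-10a-5p (15 of 16) and -0.77 ± 0.25 for miR-339 (0 of 16), each at an adjusted p of 0.541. miR-339-5p was at -0.63 ± 0.21 (adjusted p = 0.566), miR-152 at -0.49 ± 0.19 and miR-532-5p at 0.51 ± 0.20 (both adjusted p = 0.603). On the deposited values limma gave 0.69 ± 0.89 for miR-148a-3p and -0.79 ± 0.94 for miR-339. These miRNAs were chosen after their values were seen, by the smallest edgeR p. The fixed rule named 10 others by limma's p, all of which lay at the floor in at least 1 library. miR-490-5p, the first of them, had 11 reads in the deepest PND2R library and at most 2 in the other 3, and was at the floor in 3 of the 4 PND2N libraries. miR-129a-5p and its near-copy row miR-129b, whose counts were almost the same in every library, stood at 45.7 ± 23.9 rpm in PND2N and 10.7 ± 14.1 in PND2R for the first. This difference rests on shallow libraries, with 3 reads in PND2N replicate 2 and 0 in PND2R replicates 2 and 3; with the reads of each group's 4 libraries pooled the levels were 31.6 and 29.1 rpm. The edgeR adjusted p of the 10, which also held miR-345-5p, miR-490-3p, miR-452, miR-182, miR-193a-5p, miR-582 and miR-2483, was 0.614 to 0.928.

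Of the 7 rows of the miR-130 and miR-148 families 0 passed by limma and 1, miR-148a-3p, by edgeR when adjusted over the list alone. In the list of miRNAs abundant in milk, 0 of 21 rows passed by either tool, also adjusted over the list alone; 15 lay above 0 and 6 below on recovered reads (edgeR median 0.16), with miR-146b at 2321 ± 734 against 1799.6 ± 349 rpm. The 9 rows of HOX cluster miRNAs, which are 6 names, gave 0 by either tool as well; 7 lay above 0 and 2 below by edgeR, the latter both rows of miR-196b-5p (2571 against 3159 rpm), with miR-10b at 53212 ± 10710.5 against 42679 ± 8074 rpm and miR-196a at 359 ± 152 against 231 ± 78.5 (edgeR median 0.58). The 4 members of the miR-15 and miR-16 family, which restrains the cell cycle, were all below 0 and 0 passed: miR-16 stood at 1531 ± 142 against 2130.0 ± 104 rpm and miR-15b at 253 ± 74.6 against 416 ± 128.

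On the deposited values camera called 0 of 22 lists between PND2N and PND2R, with 2 at an unadjusted p under 0.05 (smallest adjusted p = 0.417). With voom on recovered reads, chosen after seeing the data, it called 3 with 5 at an unadjusted p under 0.05: milk and HOX cluster miRNAs higher and the miR-15 and miR-16 family lower in PND2N, each at an adjusted p of 0.00701. With an estimated correlation their adjusted p was 0.592 for milk, 0.275 for HOX and 0.275 for miR-15 and miR-16. The milk call ended without PND2N replicate 1, PND2N replicate 3 or PND2R replicate 3, the HOX call without PND2N replicate 3 (adjusted p up to 0.0640 for both lists), and the miR-15 and miR-16 call without PND2N replicate 3 or PND2R replicate 4 (up to 0.353).

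For PND2N against PND2R, limma passed 0 of the 268 rows in this comparison, with 4 at an unadjusted p under 0.05. Chance gives 13.4 for independent rows, but rows can vary together. Of 35 splits of these libraries 19 gave at least as many, and another split gave up to 216. On recovered reads edgeR passed 0 (with 20 at an unadjusted p under 0.05, reached in 8 of 35 splits), limma voom 0 (23) and DESeq2 0 (18). The smallest adjusted p values were 0.999, 0.541, 0.529 and 0.192 in that order of tools. Depth and feeding partly coincide here, as 3 of the 4 PND2R libraries are shallow. In data simulated at these depths limma recovered 0% of 2-fold, 9.28% of 4-fold and 61.6% of 8-fold changes, and edgeR 54.2%, 90.7% and 97.0%.

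In replacer-fed gilts against newborns, miR-206 again had the smallest limma p, at 5.52 ± 6.65 rpm (SD, n = 4) in PND2R against 26.2 ± 9.35 in PND0. miR-18a, of the miR-17 cluster, stood at 130.1 ± 14.1 against 70.5 ± 12.2 rpm and the mesenchymal miR-214 at 1752 ± 223 against 1195 ± 84.8, both above in 16 of 16 pairs of libraries. miR-1468 stood at 134 ± 13.3 against 243 ± 76.0 rpm and the more abundant of 2 rows of the HOX cluster miRNA miR-196a at 231 ± 78.5 against 426 ± 98.2, both above in 0 of 16 pairs. None passed over all rows.

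The log2 fold change of miR-206 was -1.68 ± 0.61 by edgeR (adjusted p = 0.453), and its adjusted p by limma was 0.846. By edgeR miR-18a was at 0.84 ± 0.25 (adjusted p = 0.320), and miR-214 at 0.57 ± 0.21, miR-1468 at -0.79 ± 0.28 and miR-196a at -0.80 ± 0.30 each had an adjusted p of 0.453. These 4 were chosen after their values were seen. On deposited values limma gave miR-214 the other sign, at -0.06 ± 0.89, where the median over all rows was -0.58. It gave 0.28 ± 1.09 for miR-18a, -1.40 ± 1.06 for miR-1468 and -1.53 ± 1.01 for miR-196a. The fixed rule also named miR-193a-5p, miR-184, miR-490-5p, miR-551a, miR-30c-1-3p, miR-27b-5p, miR-129a-5p, miR-326 and miR-129b, with edgeR adjusted p of 0.453 to 0.935. miR-206 was at the floor in PND2R replicates 2 and 3 and had 1 read in replicate 1, and the other 9 were at the floor in at least 1 library: miR-193a-5p stood at 20.5 ± 25.8 against 62.6 ± 24.3 rpm and miR-184 at 16.8 ± 20.1 against 42.3 ± 7.77, each with PND2R replicates 2 and 3 at the floor.

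Of the 8 striated muscle rows, limma passed 1, miR-206, and edgeR 5 when adjusted over the list alone. miR-206 was the lower one of the 5 in PND2R. miR-1 stood at 3140.0 ± 729.6 against 2167 ± 507 rpm, and the miR-133a-3p row named here at 208 ± 42.5 against 124 ± 28.8. By limma on deposited values miR-1 had a log2 fold change of -0.07 ± 0.87 and this miR-133a-3p row 0.14 ± 1.08. On deposited values the list's median was 0.07 and its mean -0.27, which differ in sign. The 5 also held a second row of miR-133a-3p and miR-133b, which differ little in sequence, so their counts are uncertain. By edgeR 2 rows of miR-194b-5p, near the floor, passed adjusted over the epithelial or the liver and gut list alone, and 0 by limma. In the let-7 and miR-98 family, a family tied to maturation in many animals, 0 of 11 rows passed by either tool, also adjusted over the list alone. By edgeR 10 of the 11 were below 0 (median -0.18), with let-7f at 19562 ± 849 against 24696 ± 2791 rpm and miR-98 at 739 ± 81.0 against 961 ± 170.4; related let-7 members can share reads. HOX cluster miRNAs gave 0 of 9 rows with all 9 below 0 by edgeR (median -0.40) and 7 by voom, among them miR-10a-5p at 6137 ± 1339 against 8230.1 ± 1587 rpm. The erythroid and blood miRNAs gave 0 of 6 rows, with 5 below 0 and 1 above by edgeR (median -0.62): the one above was miR-16, the list's most abundant member, at 2130.0 ± 104 against 1669 ± 328 rpm, and among the others were miR-451, a red cell miRNA, at 224 ± 120.4 against 337 ± 90.6 rpm and miR-486 at 10.1 ± 6.77 against 19.5 ± 4.68.

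On the deposited values camera called 0 of 22 lists between PND2R and PND0, with 3 at an unadjusted p under 0.05 (smallest adjusted p = 0.134). With voom on recovered reads it called 4, with 7 at an unadjusted p under 0.05. The let-7 and miR-98 family (adjusted p = 0.00102), HOX cluster (0.0343) and erythroid (0.0363) lists were lower and the striated muscle list (0.0429) higher in PND2R. With an estimated correlation the adjusted p was 0.312 for each of the 3 lower lists and 0.658 for striated muscle. The let-7 call held in all 12 fits that left out 1 library (adjusted p 5.61e-05 to 0.0219). The HOX call ended without PND0 replicate 3 (adjusted p = 0.0985), and the erythroid call without PND0 replicate 2, PND0 replicate 3 or PND2R replicate 4 (up to 0.321). The striated muscle call ended without PND0 replicate 3, PND2N replicate 2 or PND2R replicate 1, 3 or 4 (up to 0.444). On single rows per name the HOX and striated muscle calls ended (adjusted p = 0.0724 and 0.340). The let-7 and erythroid calls held there (0.0134 and 0.0285).

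**Figure D3:**
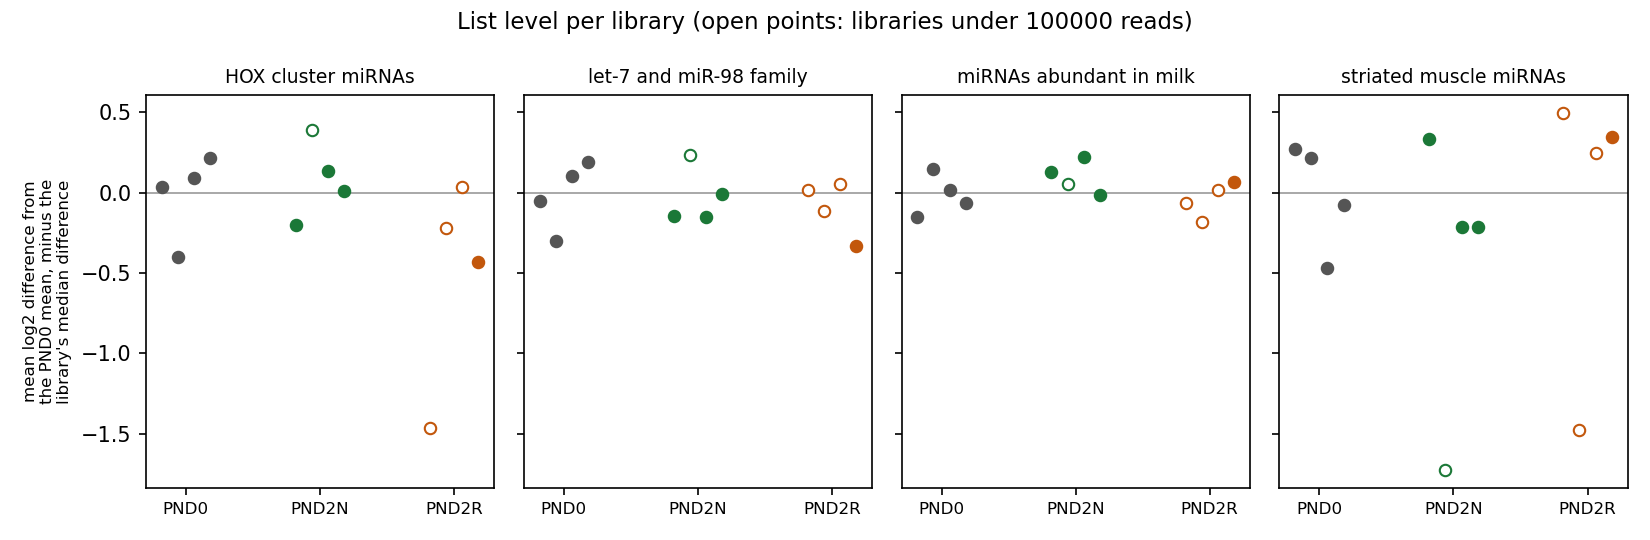
Mean log2 difference of each library from the PND0 mean over the members of 4 lists, less the library's median difference, on log2 levels of recovered reads. Points are the 4 libraries of each group and open points those under 100000 reads. The deep PND2R library lies at -0.43 for HOX cluster miRNAs and the shallow PND2R replicate 1 at -1.46.

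For PND2R against PND0, limma passed 0 of the 268 rows in this comparison, with 6 at an unadjusted p under 0.05. Chance gives 13.4 for independent rows, but rows can vary together. Of 35 splits of these libraries 10 gave at least as many, and another split gave up to 127. On recovered reads edgeR passed 0 (with 28 at an unadjusted p under 0.05, reached in 8 of 35 splits), limma voom 0 (36) and DESeq2 0 (18). The smallest adjusted p values were 0.846, 0.103, 0.291 and 0.545 in that order of tools. That of edgeR belonged to miR-194b-5p, near the floor. The median log2 fold change over all rows was -0.58 on deposited values and 0.02 on recovered reads. In data simulated at these depths limma recovered 0% of 2-fold, 13.4% of 4-fold and 48.5% of 8-fold changes, and edgeR 47.4%, 90.7% and 97.0%.

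The age comparisons of nursed and of replacer-fed gilts shared miR-206 as the miRNA with the smallest limma p, which it was in neither by edgeR, and 0 rows passed in either by limma or edgeR, so that their calls had no overlap to test. Across the 268 rows, which are not independent replicates, their log2 fold changes correlated at r = 0.434, and 85.1% had the same sign. Both use the same 4 PND0 libraries, and unchanged groups simulated against shared controls gave a mean r of 0.482 and 68.2% of equal signs over 1000 draws. The excess of equal signs came with the shifted centre: re-centred values gave 65.3% against 66.9% simulated, and recovered reads 58.2% against 66.7%. The covariance was 0.0844 against 0.107 simulated, a difference of -0.0230. With the PND0 libraries split between the comparisons, r averaged 0.104 over 6 arrangements. The nursed and replacer-fed age effects themselves differ by PND2N against PND2R, in which 0 rows passed by limma and edgeR as given above.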

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

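The results given here are those in which 1 library of a group of 4 stood apart from the other 3, with the gap to its nearest neighbour given as a share of the group's whole range; no explanation test was run for them. Of 123 sets of 4 values, 13 stood apart. Chance flags about 1 in 20 sets of independent continuous values, but several sets here tie at the floor and miR-9 and miR-9-1 are near-copies, so no excess over chance is read from the count.

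PND2R replicate 4 stood apart in depth, with 9395582 reads against 47992 to 74799 (share 0.997), and in its normalized total, 1048570 against 183915 to 325075 (share 0.837). The same library stood apart in the normalized values of miR-135 (259 against 34.2 to 40.6; share 0.917), of miR-9 (203 against 35.1 to 40.6; share 0.917) and of miR-9-1 (203 against 35.1 to 40.6; share 0.917). In rpm these were 247 against 120.3 to 186 for miR-135 and 193 against 120.3 to 201 for miR-9. miR-30c-1-3p, miR-326 and miR-582 were above the floor in that PND2R library alone (share 1 each), at 5.75, 3.83 and 15.4 rpm, levels below 1 read in each of the other 3 libraries except for miR-582 in replicates 1 and 2.

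miR-202-5p stood apart in PND2R replicate 3 (20.8 rpm from 1 read, against at most 1.17; share 0.921) and in PND2N replicate 1 (1.10 rpm with the other 3 at the floor; share 1). miR-490-5p stood apart in PND0 replicate 1 (8.61 rpm from 4 reads, against at most 2.66; share 0.856) and in PND2N replicate 3 (1.07 rpm with the other 3 at the floor; share 1). miR-345-5p stood apart in PND2R replicate 2, at the floor against 6.92 to 26.7 rpm in the other 3 (share 0.917).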

How the results depend on the processing

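The tests on recovered reads (except DESeq2), those without the 4 libraries under 100000 reads and those with single rows per name were chosen after the result was seen. Depth limits most values: 1 read is worth up to 26.7 rpm. The count of 0 rows passing held in all 33 alternatives for PND2N against PND0 (limma, edgeR, voom and DESeq2, with 0 to 31 at an unadjusted p under 0.05), and in 32 of 33 for the other comparisons. The exception was limma's library weights, with 228 rows for PND2N against PND2R and 62 for PND2R against PND0; the weights were 3.79 and 4.96 for the deep PND2N replicates 1 and 3 but 0.197 for the deep PND2R library and 2.86 for the shallow PND2R replicate 1, so they did not follow depth; the cause was not tested. With 1 library left out 0 rows passed in each comparison. No paired analysis was possible because the labels give no shared replicate numbers. Fits without the 4 shallow libraries leave a single PND2R library, so their values for comparisons with PND2R test 1 animal against a spread taken from the other groups. A restriction to miRNA rows was not run, because all rows are miRNAs.

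Called lists for PND2N against PND0 numbered 0 with the correlation estimated, with fry, after re-centring, with voom with either correlation, without the 4 shallow libraries (limma and voom) and on single rows per name (limma and voom), and 0 to 3 with 1 library left out. For PND2N against PND2R they numbered 3 with voom, 1 without the 4 shallow libraries (2 with voom) and 3 with voom on single rows per name. For PND2R against PND0 they numbered 3 after re-centring, 4 with voom, 2 with voom without the 4 shallow libraries and 2 with voom on single rows per name, and 0 to 3 with 1 library left out. In each case the cause was not tested. For the shared direction of the age effects the correlation was 0.368 among the more abundant rows, 0.753 by edgeR (for which no unchanged groups were simulated; log2 levels of recovered reads gave 0.317 against a simulated mean of 0.491), 0.343 to 0.534 with 1 library left out, and -0.00325, 0.0739, 0.324, 0.191, 0.0174, 0.0228 in the 6 arrangements that split PND0, which share no control.

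Of 1104 values of 34 named results under alternatives, 1041 kept their direction and side of the threshold, 16 were stronger, all with library weights, and 47 log2 fold changes had the other sign; the cause was not tested. With 1 library left out, miR-9 ranged from -1.20 to 0.0312 and miR-9-1 from -1.18 to 0.0527 for PND2N against PND0. After re-centring these were, for PND2N against PND0 miR-137 (0.0392). After quantile normalization these were, for PND2N against PND0 miR-9-1 (0.0480). With DESeq2 these were, for PND2N against PND0 miR-9 (0.0235), miR-9-1 (0.0431). With library weights these were, for PND2N against PND0 miR-135 (0.49), miR-205 (0.18), miR-139-3p (0.26), miR-708-5p (0.65), miR-17-3p (0.35), miR-137 (0.19), miR-218-5p (0.39), miR-9 (0.71), miR-9-1 (0.71), and for PND2N against PND2R miR-182 (0.23), miR-2483 (0.0523). Without PND2N replicate 2 these were, for PND2N against PND0 miR-9 (0.0312), miR-9-1 (0.0527). With edgeR these were, for PND2N against PND0 miR-9 (0.0457), miR-9-1 (0.0651), and for PND2N against PND2R miR-582 (-0.31). With voom these were, for PND2N against PND2R miR-582 (-0.39), and for PND2R against PND0 miR-129a-5p (0.0435), miR-129b (0.0607). Without the 4 shallow libraries these were, for PND2N against PND0 miR-9 (0.0312), miR-9-1 (0.0527), and for PND2N against PND2R miR-129a-5p (-0.61), miR-129b (-0.62), miR-490-3p (-0.59), miR-193a-5p (-0.76), miR-582 (-1.48), and for PND2R against PND0 miR-184 (0.27), miR-490-5p (-0.10), miR-30c-1-3p (0.24), miR-27b-5p (0.24), miR-129a-5p (1.01), miR-326 (0.0140), miR-129b (1.03). With edgeR without those 4 these were, for PND2N against PND0 miR-9 (0.0979), miR-9-1 (0.12), and for PND2N against PND2R miR-582 (-0.71), miR-2483 (0.30), and for PND2R against PND0 miR-490-5p (-0.0194), miR-129a-5p (0.21), miR-129b (0.23). With edgeR on single rows per name these were, for PND2N against PND0 miR-9 (0.0289), miR-9-1 (0.0478), and for PND2N against PND2R miR-582 (-0.35).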

Other observations

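The tests of the neural list, of miR-206, of the HOX and let-7 lists and of the level of the milk list were chosen after the results were seen, as were all splits on recovered reads.

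miR-339 and miR-339-5p stood lower in nursed gilts than in both other groups, with PND2N below PND0 and PND2R in 16 of 16 pairs each, although neither passed over all rows by limma or edgeR. miR-532-5p stood at 634 ± 76.0 rpm in PND2N, 562 ± 23.1 in PND0 and 476 ± 52.1 in PND2R, and miR-99b at 2469 ± 156, 2149 ± 296 and 1975 ± 242. let-7d-5p had 1719.8 ± 293 rpm at birth, 1104 ± 292 in nursed and 1342 ± 144 in replacer-fed gilts, and miR-145-5p of smooth muscle had 7329.9 ± 2569.6, 9687 ± 5776 and 13201 ± 5539. None passed, and apart from miR-339, which the fixed rule named for PND2N against PND0, they were chosen after their values were seen.

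In the remaining lists, 0 rows passed in any comparison by limma or edgeR, also adjusted over the list alone. For PND2N against PND0, PND2N against PND2R and PND2R against PND0 in turn, the imprinted DLK1-DIO3 cluster (7 rows) had edgeR medians of 0.01, -0.37 and 0.21. In the last all 7 were above 0 by edgeR, but on deposited values 2 were above and 5 below. The list's median there was -0.25, against -0.58 over all rows. Leukocyte miRNAs (7 rows) had edgeR medians of 0.08, -0.19 and 0.29, endothelial miRNAs (14) -0.09, -0.08 and 0.02, the miR-23, miR-24 and miR-27 clusters (9) -0.03, -0.08 and 0.05, and the miR-181 family (6) -0.14, 0.16 and -0.31. The miR-29 family (4) had -0.20, 0.03 and -0.23, the miR-30 family (11) 0.05, 0.20 and 0.07, the miR-99, miR-100 and miR-125 group (5) 0.34, 0.43 and -0.10, and miR-221 and miR-222 (3) -0.21, -0.19 and 0.02. The X-linked miR-424 and miR-503 cluster had 0 measured rows and the miR-34 and miR-449 family 1, so neither was tested.

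The lower level of miR-206 in PND2 does not rest on shallow libraries alone. In the libraries over 1000000 reads, 220 reads in 3 PND2 libraries against 423 in 2 PND0 libraries gave a ratio of 0.276 (95% counting interval 0.234 to 0.326). PND2R replicate 4 was the only PND2R library among the 3, so for replacer-fed gilts this rests on a single animal. Over the 8 libraries above 200000 reads every PND0 library exceeded every PND2 library (two-sided exact permutation p = 0.0286 over 70 splits, for a miRNA picked for its small p). The gap was narrow, with a lowest PND0 level of 13.3 rpm and a highest PND2 level of 11.8. Chance as the smallest of many p values stays open, since 14 of 35 splits of these libraries gave as small a smallest p by limma on log2 levels of recovered reads (smallest adjusted p = 0.636 in the real split, led by miR-1, and 0.0471 in the lowest other). Skeletal muscle carried over with PND0 tissue may be a source, but miR-1, miR-133a and miR-133b had a median log2 fold change of 0.61 over both PND2 groups. miR-206 made up 1.06% of the 4 muscle miRNAs in PND0, too little for the more abundant miR-1 and miR-133a to decide it. miR-133b stood close to miR-206 in PND0 and went the other way. Its edgeR log2 fold change against PND0 was 0.529 ± 0.343 in PND2N and 0.904 ± 0.384 in PND2R. It had 1 or 2 reads in each library under 100000 reads, and its counts are uncertain beside miR-133a, so muscle stays open. A change with age is a further hypothesis and was not tested apart from these.

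The lower HOX and let-7 lists in PND2R against PND0 on recovered reads may reflect feeding, age or the libraries. Level stays open for let-7 (percentile 12.67 among 10000 random lists matched on level). It is not excluded for HOX, whose 9 rows are 6 names. The HOX percentile was 0.04 with voom, 0.58 on log2 levels of recovered reads and 0.48 on deposited values. On deposited values with a pseudocount of 5 it was 9.56. Joint variation of the members stays open (smaller adjusted p = 0.312 by limma voom with the correlation estimated). Depth stays open too. On log2 levels of recovered reads the 1 deep PND2R library lay at -0.43 on the HOX list and -0.33 on the let-7 list. These were just under the lowest PND0 values of -0.40 and -0.30. The shallow PND2R replicates 1 to 3 lay at -1.46, -0.22 and 0.03 on HOX and within the PND0 range on let-7 (-0.12 to 0.06), and the shallow PND2N replicate 2 at 0.39 and 0.23. Chance was not excluded, since 4 of 35 splits called as many lists (4 in the real split, at most 5 in another).

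Low level is not excluded for the upward placing of neural miRNAs in PND2N against PND0. On deposited values the list's median was at percentile 99.73 of 10000 random lists matched on level. Those lists treat rows as independent, while the 18 neural rows are 15 names with near-copies such as miR-9 and miR-9-1. On single rows per name camera did not call the list (adjusted p = 0.248). A shallow library given the same weight as the others is a candidate explanation, since without PND2N replicate 2 (37462 reads) the percentile was 86.11, and on recovered reads weighted by depth with voom it was 64.5. With all libraries it was 98.36 on unweighted log2 levels of recovered reads and 99.92 on deposited values with a pseudocount of 5. Chance was not excluded, since 17 of 35 splits of the 8 libraries called at least 1 list (1 in the real split, at most 3 in another).

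The counts of rows passing by limma cannot be set against chance, because with a real count of 0 all 35 splits give at least as many whatever the data. The highest count of another split was 201 for PND2N and PND0, 209 for PND2N and PND2R and 4 for PND2R and PND0, and by edgeR on recovered reads 20, 1 and 3. The split with 201 set the 4 libraries of 37462 to 464476 reads against the 4 of 3561682 to 12159233, which points to a structure of the samples by depth in the deposited values; that with 209 set PND2N replicates 1 and 3 and PND2R replicates 3 and 4 against the rest. The 0 called lists of PND2N against PND2R and of PND2R against PND0 cannot be set against chance for the same reason, and another split called at most 3 in each. On recovered reads with voom, chance was not excluded for the 3 lists called for PND2N against PND2R, since 17 of 35 splits called as many (3 in the real split, at most 5 in another). Among 10000 random lists matched on level, the milk list's median lay at percentile 97.95 with voom and 98.81 on log2 levels of recovered reads. On deposited values it was 98.73, and 99.21 with a pseudocount of 5. Those lists treat rows as independent, while the 21 milk rows are 18 names, so level was not excluded.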
